A study of Mus musculus with 14 samples.

How the data were processed

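Triceps muscle of male mice was profiled by 3′-end RNA sequencing (QuantSeq FWD libraries, which read the 3′ end of each transcript) in 14 animals. The mice were FLExDUX4, which carry a human DUX4 transgene and serve as a model of facioscapulohumeral muscular dystrophy (FSHD), or their WT littermates. Mice of each genotype had either 6 weeks of voluntary wheel running or no wheel. Per the labels, there were 4 FLExDUX4 runners, 4 WT runners, 3 FLExDUX4 controls and 3 WT controls, and replicates are numbered in the order of the sample records.

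The deposited table held raw read counts per gene and per spike-in for each mouse, without normalization. The authors also placed in it the summed counts of each group, their log2 fold changes, the unadjusted p values and the adjusted p values of 6 group comparisons, made with DESeq2 per the submitters' notes. The group sums equalled the sums of the mice in all 52649 rows. The submitters' notes name cutadapt 1.16, FastQC 0.11.7, STAR 2.5.3a, featureCounts 1.6.2 from Subread, and DESeq2, with the builds GRCm38 and GRCh38. The annotation release, the strand setting and the handling of reads with several alignments were not given in the sources used here. Of the 52550 gene identifiers, 52403 were found in GENCODE M21 on GRCm38, all on the listed chromosome, and 96.5% had the same start. Coordinates are given on that build.

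The analysis started from the counts per mouse. The 92 ERCC and 7 SIRV spike-in sequences were set aside, which left 52550 genes, 20938 of them with at least 1 count. Total counts per library ran from 3315921 in WT control 3 to 7089226 in FLExDUX4 control 3, so that 1 CPM (read counts scaled to library size) stood for 3 to 7 reads. No pair of replicates looked like a duplicate: the lowest chi-square per degree of freedom between replicates was 5.89. The sequencing reads carry no molecular identifiers in the files used here, so floors and counting errors cover counting only.

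Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled with TMM factors, and genes were kept by filterByExpr with a minimum count of 10, which left 11088. Then 1 quasi-likelihood fit with robust spread estimates and 1 mean per group covered all 14 libraries. The common biological coefficient of variation was 0.288. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The 7 contrasts were genotype in controls, running in FLExDUX4, running in WT, genotype in runners, the difference of the running effects (the interaction), genotype averaged over running, and running averaged over genotype. CPM values are given as mean ± SD over the mice of a group, and log2 fold changes with the standard error of the fit.

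Before the data were examined, 37 gene lists were fixed: muscle fibre types, energy metabolism, stress and growth programmes, markers of other cell types, and genes reported to respond to DUX4. The 33 lists with at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, 2-sided, adjusted over the 33 lists. Each list was tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. Members were counted after adjustment over all genes and adjusted over the list alone.

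The rule for naming genes was also fixed beforehand. In each comparison it took the 8 highest and 8 lowest fold changes among called genes whose groups did not overlap and whose higher group averaged at least 5 CPM, leaving out symbols made of Gm and digits or ending in Rik. The overlap condition was dropped for the interaction and the averages. It added up to 4 members of each list with the smallest p past 0.05 adjusted over the list alone. Ppargc1a, Myh7, Myh2, Myh1, Myh4, Myh3, Pax7, Cdkn1a, Col1a1, Cd68, the DUX4-responsive list and any DUX4 row were always considered. Where fewer than 5 genes met the first condition, the 5 with the smallest p were added and are said to be uncalled. A gene named outside this rule is marked as chosen after its values were seen.

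The alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper quartile factors, no low-count filter, a filter of 1 CPM in 3 libraries, no robust estimate, an adjusted p threshold of 0.10, 1 surrogate variable from sva 3.50.0, only the 2 groups compared, and each mouse left out in turn. After the data were seen, 4 more were added: counts without mitochondrial genes and Gm42418, library sizes from the spike-ins, FLExDUX4 control 1 and WT running 2 left out together, and the level of the slow fibre genes as a covariate. Per-mouse measures were compared with 2-sided exact permutation tests, within genotype or within running for the averages, adjusted over 54 such tests. The smallest 2-sided p that such a test can reach is 0.10 for 3 against 3 mice and 0.0286 for 4 against 3.

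Recovery was tested on simulated data with the group sizes of the design, 11088 genes and 200 changed ones. Of the 4-fold changes, 62.1% were called for genotype in controls, 66.7% for running in WT, 39.4% for the interaction and 83.3% for running averaged over genotype. Of the 2-fold changes, the shares were 25.4%, 32.8%, 2.99% and 68.7%. The authors' comparisons of FLExDUX4 controls with WT runners and of FLExDUX4 runners with WT controls, which change genotype and running at once, were not tested here.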

Results

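The data were gene counts from the triceps of 14 male mice in 4 groups: FLExDUX4 and WT littermates, each with 6 weeks of voluntary wheel running (4 mice per genotype) or without (3 mice per genotype). By the title of the series, the study asked whether aerobic exercise improves molecular and functional deficits of the FLExDUX4 model. Library totals were 3992973 to 7089226 counts in FLExDUX4 controls, 3315921 to 4731380 in WT controls, 3475940 to 6757914 in FLExDUX4 runners and 4769278 to 6158357 in WT runners. The muscle was of fast type. Myh4, the fast IIb myosin heavy chain, averaged 98.6% ± 0.256 (SD, n = 3) of the summed Myh7, Myh2, Myh1 and Myh4 counts in WT controls. Transcripts of the mitochondrial genome took 24.0% ± 2.82 of gene counts in WT controls, 26.2% ± 4.88 in FLExDUX4 controls, 31.8% ± 4.01 in WT runners and 33.2% ± 5.40 in FLExDUX4 runners. Averaged over genotype, runners were higher by 7.36 percentage points (exact permutation p = 0.0106, adjusted p = 0.154 over 54 tests).

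DUX4, the transcription factor whose expression in muscle underlies FSHD, had no row among the genes analysed here, so transgene expression could not be checked directly. Of 7 mouse genes fixed beforehand as DUX4-responsive, only Sord and Ilvbl had enough counts for a test. Sord, sorbitol dehydrogenase, averaged 37.2 CPM ± 4.83 (n = 3) in WT controls and 40.9 ± 3.68 (n = 3) in FLExDUX4 controls, a log2 difference of 0.14 ± 0.20 (edgeR adjusted p = 0.999). Ilvbl differed by -0.25 ± 0.42 (adjusted p = 0.999). In runners, the genotype differences were 0.37 ± 0.17 for Sord and -0.01 ± 0.36 for Ilvbl, again uncalled (adjusted p = 0.999 for each). Serpinb6c had 5 counts in FLExDUX4 controls, all in mouse 3, 11 in FLExDUX4 runners, 10 of them in mouse 1, and 0 in both WT groups, and Wfdc3 had 1 count in all. Trim36 had 11 counts in the runners of each genotype, all 11 in WT running 2 and 9 in FLExDUX4 running 4, and 0 in either control group. Slc15a2 had 60 counts in all, and Slc34a2 had 0. No count fell on the 15 early-embryo genes of the mouse Dux network found in the table. Why the 5 untested DUX4-responsive genes and the Dux network genes had few or no counts was not tested. Depth, a lack of expression and the handling of reads with several alignments, which was not given, all remain possible.

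Genotype without running was read from FLExDUX4 controls against WT controls. Slow fibre, tendon and fatty acid oxidation genes sat higher in FLExDUX4 controls as lists, while no single gene was called. These list calls rest on the preset correlation of 0.01 between genes. The estimated correlation was 0.76 for slow fibre, 0.51 for tendon and 0.49 for fatty acid genes. With estimated correlations, 0 lists were called in this or any other of the 7 comparisons, so the small camera p values hold only at the preset value. The 13 slow fibre contractile genes had a median log2 difference of 2.22, with 12 of 13 above 0 and 0 past the threshold adjusted over the list alone (camera adjusted p = 7.06e-08; adjusted p = 0.626 with an estimated correlation). Myh7, the slow myosin, averaged 15.9 CPM ± 17.7 (n = 3) against 2.28 ± 1.74 (n = 3), and Myh2, the IIa myosin of oxidative fast fibres, 504 ± 77.5 against 63.6 ± 13.9, both uncalled (adjusted p = 0.972 and 0.969). Of 7 tendon markers, 6 were higher adjusted over the list alone and 0 over all genes. Their median was 1.15 (camera adjusted p = 5.98e-09; adjusted p = 0.278 with an estimated correlation).

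**Figure D1:**
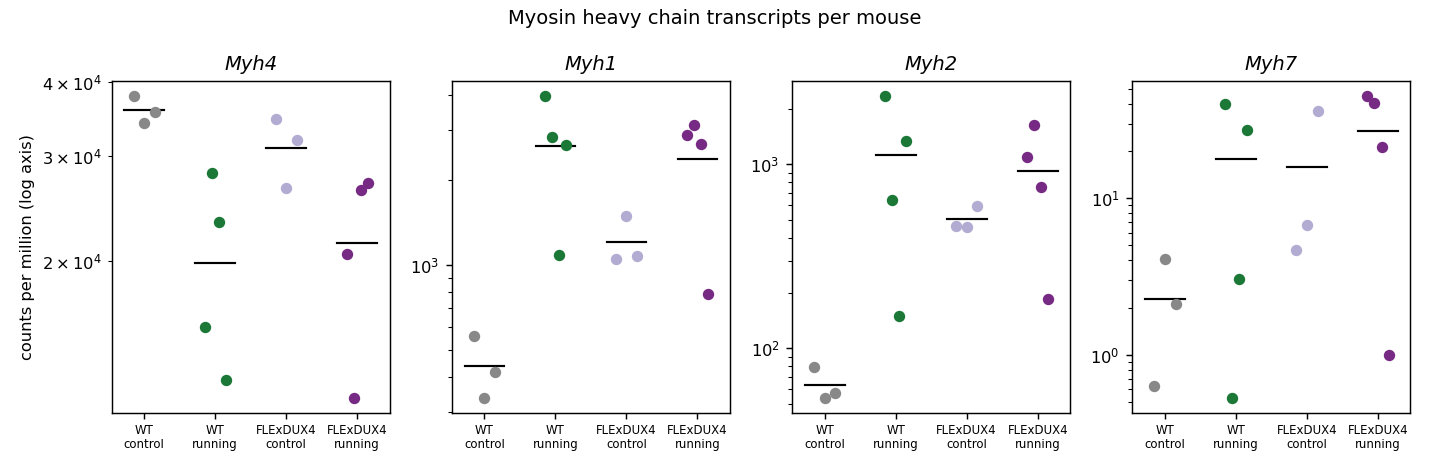
CPM of the 4 adult myosin heavy chain transcripts in each mouse, on a log axis, by group. Points are mice and bars are group means; Myh2 averaged 63.6 CPM in WT controls, 1119 in WT runners, 504 in FLExDUX4 controls and 921 in FLExDUX4 runners.

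Among the tendon markers, the cartilage and tendon matrix protein gene Chad was 2.41 ± 0.53 higher on the log2 scale (18.2 CPM ± 2.62 against 3.45 ± 1.89, adjusted p = 0.464). Thbs4 differed by 0.87 ± 0.27, Cilp2 by 2.21 ± 0.70 and Tnmd by 1.15 ± 0.46 (adjusted p = 0.969 for each). Scx, a transcription factor of tendon cells named after its value was seen, differed by -0.17 ± 0.56. Col1a1, the main fibrillar collagen, differed by 0.19 ± 0.22 (adjusted p = 0.999). The 26 genes of fatty acid uptake and oxidation had a median of 0.39 (camera adjusted p = 1.42e-07; adjusted p = 0.626 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. The 24 glycolysis and glycogen genes had a median of -0.22 (camera adjusted p = 0.000543; adjusted p = 0.658 with an estimated correlation), a sign that turned to 0.08 with library sizes from the spike-ins. The camera test also placed 4 other lists higher. These were the respiratory chain (median 0.12, adjusted p = 0.00825), smooth muscle and pericyte markers (0.25, 0.0118), endothelial markers (0.40, 0.0126) and regulators of mitochondrial biogenesis and endurance (0.12, 0.0357). With an estimated correlation their adjusted p were 0.991, 0.383, 0.626 and 0.658. Adjusted over the list alone, Acta2, smooth muscle actin, was 1.00 ± 0.27 higher, and Ppara, a transcription factor of lipid oxidation, 1.71 ± 0.39 higher. Over all genes, their adjusted p were 0.73 and 0.407.

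edgeR called 0 of 11088 genes in this comparison, with 554 at an unadjusted p under 0.05 where chance gives 554.4. This 0 belongs to the fit of all 14 libraries, in which the control groups share 1 estimate of spread with the runners. With only the 2 control groups in the fit, some genes were called, as counted in the part on processing. DESeq2 called 3 genes, all higher in FLExDUX4 controls and named after their values were seen: Chad, Pim3 and Myom3. limma-voom called 0. The authors' table held 1 call for this pair, Pim3, higher in FLExDUX4 controls. With edgeR, the 5 smallest p, all uncalled, belonged to Pim3, Pdlim1, Ppara, Chad and Phldb1. Pim3 (ENSMUSG00000035828, chromosome 15, 88862186 to 88865726), a serine/threonine kinase, averaged 48.1 CPM ± 20.5 (n = 3) against 19.5 ± 4.63 (n = 3), a log2 difference of 1.29 ± 0.26 (adjusted p = 0.347). It was called without FLExDUX4 control 3 (1.50, adjusted p = 0.0277). Pdlim1, a scaffold protein of the actin cytoskeleton, differed by 1.71 ± 0.38 (adjusted p = 0.382), and Phldb1 by 1.33 ± 0.33 (adjusted p = 0.612). Ppargc1a, the coactivator of mitochondrial biogenesis, differed by 0.58 ± 0.20 (adjusted p = 0.969). Myh1 differed by 1.46 ± 0.53, Myh4 by -0.21 ± 0.30, the satellite cell gene Pax7 by 0.89 ± 0.71, the cell cycle inhibitor gene Cdkn1a by 0.53 ± 0.40 and the macrophage gene Cd68 by -1.44 ± 0.93, all uncalled. The embryonic myosin gene Myh3 had too few counts to be tested. Library sizes from the spike-ins moved the median of all genes by 0.31, because spike-ins took 1.404% ± 0.124 of counts in WT controls and 1.12% ± 0.180 in FLExDUX4 controls.

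Running in WT mice was read from WT runners against WT controls. Genes of mitochondrial respiration and fatty acid oxidation rose together, slow fibre and endothelial genes were higher, and fast fibre, glycolytic and clock genes were lower. Of 77 nuclear-encoded genes of the respiratory chain and ATP synthase, 57 rose adjusted over the list alone and 8 over all genes, with a median log2 change of 0.46 (camera adjusted p = 2.06e-32; adjusted p = 0.229 with an estimated correlation). Of 26 fatty acid genes, 22 rose adjusted over the list alone and 5 over all genes, with a median of 0.89 (camera adjusted p = 1.56e-28; adjusted p = 0.103 with an estimated correlation; fry adjusted p = 0.0413). Beside these groups, the mitochondrial share of counts was 7.74 percentage points higher in WT runners (exact permutation p = 0.0571) and the mean log2 level of the slow fibre genes was 2.15 higher (exact permutation p = 0.0571).

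In the respiratory chain list, Atp5g1, a c subunit of ATP synthase, rose by 0.84 ± 0.18 (168 CPM ± 8.22, n = 3, to 301 ± 64.8, n = 4; adjusted p = 0.0292), and Cox7a1, a muscle form of a cytochrome c oxidase subunit, by 0.84 ± 0.18 (adjusted p = 0.0388). Atp5g3 rose by 0.71 ± 0.16 and Cyc1, cytochrome c1, by 0.66 ± 0.16 (adjusted p = 0.0411 and 0.0458). Among the fatty acid genes, Slc25a20 (ENSMUSG00000032602, chromosome 9, 108662088 to 108684641), the carnitine-acylcarnitine carrier of mitochondria, rose by 1.08 ± 0.21, from 29.98 CPM ± 3.29 to 63.2 ± 14.04 (adjusted p = 0.0194). Plin5, a coat protein of lipid droplets, rose by 2.39 ± 0.49, Hadhb, a subunit of the trifunctional protein of fatty acid oxidation, by 1.02 ± 0.22, and Etfb, which carries electrons from it, by 0.83 ± 0.18 (adjusted p = 0.028, 0.0411 and 0.0322). The 20 genes of the tricarboxylic acid cycle had a median of 0.38, with 10 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.85e-07; adjusted p = 0.233 with an estimated correlation). Among them, Sdhb differed by 0.83 ± 0.24 and Dld by 0.57 ± 0.18, uncalled over all genes (adjusted p = 0.143 and 0.153). The 10 tested mitochondrially encoded genes had a median of 0.38, with 1, mt-Co1, higher adjusted over the list alone (camera adjusted p = 0.000198; adjusted p = 0.233 with an estimated correlation).

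The fibre type genes of WT runners differed in the oxidative direction with wide spread between mice. Of 13 slow fibre genes, 4 were higher adjusted over the list alone and 0 over all genes, with a median of 2.94 (camera adjusted p = 3.33e-08; adjusted p = 0.229 with an estimated correlation). They were Casq2, calsequestrin of slow and cardiac muscle (1.89 ± 0.51), and Myoz2, Csrp3 and Ankrd2, sarcomere proteins of slow fibres (3.52 ± 0.97, 2.74 ± 0.80 and 3.52 ± 1.04), with adjusted p of 0.12 to 0.212 over all genes. Of 16 fast fibre genes, 11 were lower and 1, Myh1, was higher adjusted over the list alone, with a median of -0.44 (camera adjusted p = 3.48e-08; adjusted p = 0.229 with an estimated correlation). Casq1, Tpm1 and Sypl2 differed by -0.60 ± 0.16, -0.55 ± 0.17 and -0.49 ± 0.16, uncalled over all genes (adjusted p = 0.0656, 0.132 and 0.184). Myh4 averaged 35881 CPM ± 1911 (n = 3) in WT controls and 19850 ± 7114 (n = 4) in WT runners, Myh1 438 ± 111 and 2633 ± 1182, and Myh2 63.6 ± 13.9 and 1119 ± 953. None of these 3 passed over all genes (adjusted p = 0.223, 0.0747 and 0.108), nor did Myh7 (2.94 ± 1.63, adjusted p = 0.588). These transcripts are alike in sequence, and how reads with several alignments were handled was not given. Mb, myoglobin, averaged 361 CPM ± 26.0 and 2696 ± 1483 (2.90 ± 0.63, adjusted p = 0.0843), and Ppargc1a differed by 0.44 ± 0.19 (adjusted p = 0.364).

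**Figure D2:**
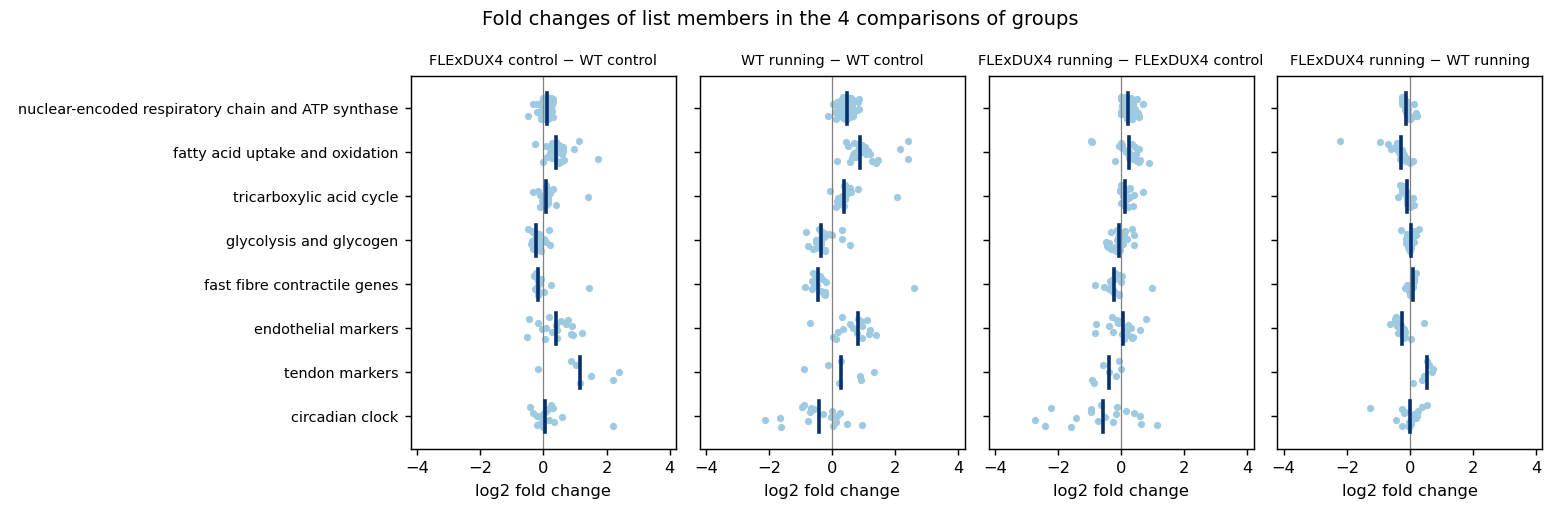
Log2 fold changes of the members of 8 fixed gene lists in the 4 comparisons of groups. Each point is a gene and each dark bar the median of its list, which in WT runners against WT controls was 0.46 for the respiratory chain, 0.89 for fatty acid oxidation and -0.44 for fast fibre genes; the negative medians of this comparison lay nearer 0 with library sizes from the spike-ins, and that of glycolysis reached 0.00.

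The 24 glycolysis and glycogen genes had a median of -0.35 in WT runners, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.92e-07; adjusted p = 0.229 with an estimated correlation). Gpd1, cytosolic glycerol-3-phosphate dehydrogenase, fell by 0.83 ± 0.17 on the log2 scale (283 CPM ± 45.7 to 159 ± 28.3, adjusted p = 0.0292). Pgm2 differed by -0.62 ± 0.18, Phkb, a phosphorylase kinase subunit, by -0.53 ± 0.16 and Gbe1, the glycogen branching enzyme, by 0.56 ± 0.19 (adjusted p = 0.103, 0.126 and 0.183). Of 18 endothelial markers, 8 rose adjusted over the list alone and 1 over all genes, with a median of 0.80 (camera adjusted p = 1.51e-07; adjusted p = 0.103 with an estimated correlation; fry adjusted p = 0.0368). Kdr, a receptor for vascular endothelial growth factor, rose by 1.21 ± 0.26 (adjusted p = 0.0411). Pecam1 differed by 0.90 ± 0.25, Esam by 0.90 ± 0.28 and Gpihbp1, which anchors lipoprotein lipase on capillaries, by 1.10 ± 0.31 (adjusted p = 0.0947, 0.13 and 0.0872). Of 6 red blood cell genes, 5 were higher adjusted over the list alone (median 1.11, camera adjusted p = 0.000209; adjusted p = 0.229 with an estimated correlation), among them Hbb-bs at 1.23 ± 0.43 and Alas2, the first enzyme of erythroid haem synthesis, at 1.56 ± 0.54, 0 of them over all genes. Of 11 smooth muscle and pericyte markers, 1 rose, the pericyte gene Rgs5 (0.68 ± 0.16, adjusted p = 0.0433), in a list with a median of 0.33 (camera adjusted p = 0.00705; adjusted p = 0.219 with an estimated correlation).

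Of 18 heat shock genes, 5 were higher adjusted over the list alone in WT runners and 1 over all genes (median 0.22, camera adjusted p = 0.000136; adjusted p = 0.229 with an estimated correlation). Hspb7, a small heat shock protein of muscle, rose by 2.27 ± 0.40 (16.4 CPM ± 4.16 to 78.9 ± 20.7, adjusted p = 0.0411), and Cryab, αB-crystallin, differed by 1.06 ± 0.25 (adjusted p = 0.0739). Of 18 clock genes, 7 were lower adjusted over the list alone and 0 over all genes (median -0.43, camera adjusted p = 0.000129; adjusted p = 0.166 with an estimated correlation). Regulators of mitochondrial biogenesis and endurance (25 genes) had a median of 0.31, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00433; adjusted p = 0.233 with an estimated correlation). Schwann cell and nerve markers had a median of 0.58, with 1 of 9, the myelin gene Mbp, higher adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.229 with an estimated correlation). Antioxidant genes were not called by camera (adjusted p = 0.137) but by fry (adjusted p = 0.0413). In that list Sod2, mitochondrial superoxide dismutase, rose by 0.64 ± 0.15 (adjusted p = 0.043). Cdkn1a differed by 1.48 ± 0.38 (adjusted p = 0.0872), Cd68 by -1.38 ± 0.84, Col1a1 by -0.21 ± 0.21 and Pax7 by 0.25 ± 0.67, all uncalled.

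Over all genes, edgeR called 55 in WT runners against WT controls, 44 higher and 11 lower, with 1182 at an unadjusted p under 0.05. The groups did not overlap for any of the 55, which adds no support, since these genes were chosen by the same difference. Of all tested genes, 10.3% did not overlap, against 5.71% by chance. The largest called rises were in Myom3 (ENSMUSG00000037139, chromosome 4, 135759715 to 135815564), an M-band protein of the sarcomere, by 4.55 ± 0.81, and in Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), a prolyl hydroxylase that acts on hypoxia-inducible factors, by 3.48 ± 0.60. Myom3 went from 0.813 CPM ± 0.498 to 20.6 ± 15.5 and Egln3 from 3.596 ± 1.08 to 39.6 ± 24.2 (adjusted p = 0.0411 for both). Slc25a34, a mitochondrial carrier, rose by 3.02 ± 0.56, Dhrs4 by 2.75 ± 0.54, the growth factor gene Fgf1 by 2.65 ± 0.47 and Dach2, a transcriptional cofactor of muscle, by 2.29 ± 0.54. Among the called falls, the actin-associated protein gene Palld fell by 0.83 ± 0.17, Nrep by 0.94 ± 0.20, Mat2a, which makes S-adenosylmethionine, by 0.80 ± 0.18, Xpr1, a phosphate exporter, by 0.69 ± 0.16 and Tigar, a regulator of glycolysis, by 0.73 ± 0.17. The mitochondrial tRNA gene mt-Tt, which adjoins mt-Cytb, fell by 2.0 ± 0.41, and the pseudogene Hmgb1-ps8 by 0.99 ± 0.24. DESeq2 called 196 genes, including all 55, and limma-voom 23, of which 10 were shared. The authors' table held 302 calls for this pair, 299 of them among the genes tested here, and 38 of the 55 were among them, all in the same direction.

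The count rested on single mice: 0 genes were called without WT control 1, 2 without WT running 4, 4 without WT control 2, 10 without WT running 1 or without WT control 3, and 197 without WT running 3. Library sizes from the spike-ins gave 604 calls, 602 higher and 2 lower, and moved the median of all genes by 0.37, so that the lower values above hold relative to the other genes.

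Running in FLExDUX4 mice was read from FLExDUX4 runners against FLExDUX4 controls. Clock genes sat lower in the runners, and respiratory chain and mitochondrially encoded genes higher, as lists, and no single gene was called. Of 18 clock genes, 7 were lower and 1 higher adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.51e-05; adjusted p = 0.198 with an estimated correlation). The repressor gene Per2 averaged 12.7 CPM ± 10.8 (n = 3) in controls and 1.96 ± 0.380 (n = 4) in runners (-2.74 ± 0.83). The clock output gene Tef (ENSMUSG00000022389, chromosome 15, 81802421 to 81826863) averaged 107 ± 24.8 and 55.5 ± 9.42 (-0.95 ± 0.20). Usp2, a deubiquitinase under clock control, differed by -0.95 ± 0.23 and the repressor gene Nr1d2 by -0.73 ± 0.20, and all 4 were uncalled over all genes (adjusted p = 0.6, 0.365, 0.519 and 0.519).

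The 77 respiratory chain genes had a median of 0.21 in FLExDUX4 runners, 74 of them above 0 and 0 past the threshold adjusted over the list alone (camera adjusted p = 2.9e-10; adjusted p = 0.783 with an estimated correlation). The 10 mitochondrially encoded genes had a median of 0.41 (camera adjusted p = 7.1e-05; adjusted p = 0.733 with an estimated correlation), beside a mitochondrial share of counts 6.97 percentage points higher (exact permutation p = 0.143). The 16 fast fibre genes had a median of -0.21, with 1 lower adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.783 with an estimated correlation). That gene was Mylk2, the skeletal myosin light chain kinase, which averaged 378 CPM ± 40.7 and 213 ± 57.0 (-0.82 ± 0.18, adjusted p = 0.365 over all genes). Lists of fatty acid oxidation (median 0.25, camera adjusted p = 0.019), the tricarboxylic acid cycle (0.12, 0.0321) and cytosolic ribosomal proteins (0.09, 0.0461) were also higher, each with an adjusted p = 0.783 with an estimated correlation and 0 members past the threshold adjusted over the list alone. Slow fibre genes were not called (median 0.70, camera adjusted p = 0.083).

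edgeR called 0 genes here, with 738 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The authors' table held 4 calls: Egln3, Tef, Usp2 and Mylk2. Besides Tef and Mylk2, the smallest p, all uncalled, were those of Timp4, an inhibitor of matrix metalloproteinases (-1.39 ± 0.32, adjusted p = 0.437), Ift20, an intraflagellar transport protein (-0.89 ± 0.22, adjusted p = 0.519), and A330023F24Rik (-1.10 ± 0.28, adjusted p = 0.519). S100a8, a neutrophil gene, differed by 2.86 ± 1.03 at 0.300 CPM ± 0.520 against 2.96 ± 1.27 and was the 1 of 5 neutrophil and mast cell markers past the threshold adjusted over the list alone. The proteasome ATPase gene Psmc5 was the 1 of 31 proteasome genes, at -0.68 ± 0.19. Neither list was called (camera adjusted p = 0.0674 and 0.0692). Myh2 differed by 0.87 ± 0.82, Myh1 by 0.97 ± 0.50, Myh4 by -0.54 ± 0.28, Myh7 by 0.67 ± 1.27, Ppargc1a by -0.12 ± 0.18, Sord by 0.39 ± 0.18 and Cdkn1a by 0.57 ± 0.36, all uncalled. Without FLExDUX4 control 2, camera called 12 lists in place of 7.

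**Figure D3:**
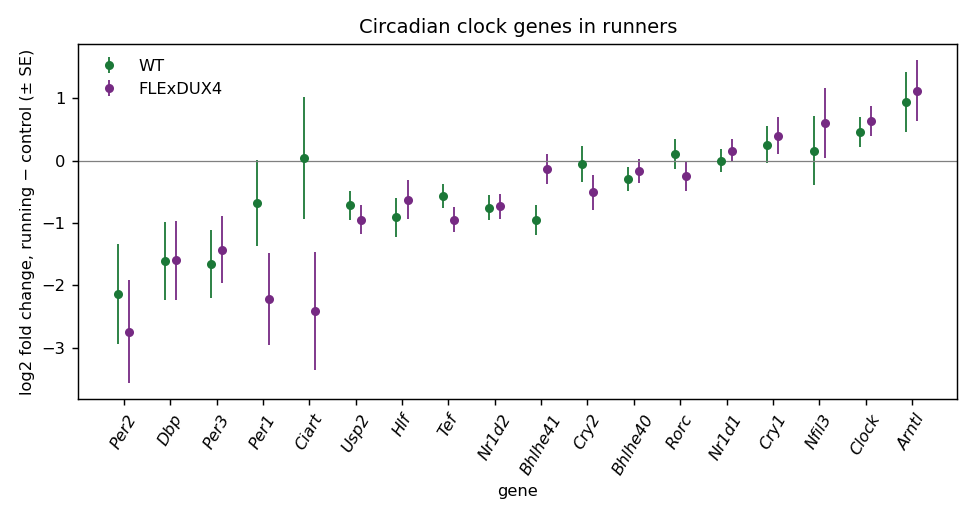
Log2 fold change of 18 circadian clock genes in runners against controls of the same genotype, with standard errors from the edgeR fit. Per2, at -2.14 in WT and -2.74 in FLExDUX4, lies lowest on average, and Arntl, named after its value was seen, at 0.95 and 1.12, highest; neither gene was called over all genes.

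Averaged over the genotypes, genes of oxidative metabolism rose in runners and clock output genes fell. Of 77 respiratory chain genes, all had a fold change above 0, 63 rose adjusted over the list alone and 12 over all genes (median 0.34, camera adjusted p = 1.32e-32; adjusted p = 0.251 with an estimated correlation; fry adjusted p = 0.0469). Of 26 fatty acid genes, 20 rose adjusted over the list alone and 7 over all genes (median 0.56, camera adjusted p = 4.74e-20; adjusted p = 0.203 with an estimated correlation; fry adjusted p = 0.0469). Of 18 clock genes, 9 fell and 2 rose adjusted over the list alone, and 3 fell over all genes (median -0.64, camera adjusted p = 8.36e-08; adjusted p = 0.0676 with an estimated correlation; fry adjusted p = 0.0255). Those 3 were Tef (-0.76 ± 0.14, adjusted p = 0.00773), Nr1d2 (-0.74 ± 0.14, adjusted p = 0.00773) and Usp2 (-0.83 ± 0.16, adjusted p = 0.028).

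edgeR called 95 genes for this average, 61 higher and 34 lower, with 1328 at an unadjusted p under 0.05; DESeq2 called 273 and limma-voom 70. Egln3 rose by 2.88 ± 0.41, to 39.6 CPM ± 24.2 (n = 4) in WT and 35.3 ± 17.4 (n = 4) in FLExDUX4 runners from 3.596 ± 1.08 and 6.97 ± 2.30 (n = 3 each; adjusted p = 0.0122). Slc25a34 rose by 2.40 ± 0.38 (adjusted p = 0.00241), Lmcd1, a LIM domain transcriptional cofactor, by 1.65 ± 0.31, Casq2 by 1.57 ± 0.35, Hspb7 by 1.50 ± 0.27, Cryab by 0.89 ± 0.17 and the matrix proteoglycan gene Bgn by 1.01 ± 0.23. In metabolism, Atp5g1 rose by 0.67 ± 0.12, Cox5b by 0.53 ± 0.11, Slc25a20 by 0.78 ± 0.15 and the triglyceride lipase gene Pnpla2 by 0.44 ± 0.10. Kdr, Rgs5 and Sod2 rose by 0.90 ± 0.18, 0.46 ± 0.11 and 0.44 ± 0.11. Mylk2 fell by 0.65 ± 0.13, Gpd1 by 0.58 ± 0.12, the lipogenic transcription factor gene Srebf1 by 0.62 ± 0.16, Tiam1 by 1.02 ± 0.25 and Rhobtb1 by 0.74 ± 0.19, and Gon4l fell by 1.13 ± 0.24. Myhas, a noncoding transcript within the fast myosin cluster, fell by 0.87 ± 0.18. It overlaps that cluster, and the strand setting of the counting was not given. Myom3, Fgf1, Iqsec2 and mt-Tt were also called, at 2.53 ± 0.51, 1.48 ± 0.31, 1.44 ± 0.32 and -1.59 ± 0.29.

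Camera called 16 of 33 lists for the average, 12 higher and 4 lower, and 0 with an estimated correlation. Slow fibre genes had a median of 2.05 and fast fibre genes of -0.28 (camera adjusted p = 2.52e-07 and 7.42e-09; adjusted p = 0.299 and 0.251 with an estimated correlation). Adjusted over the list alone, 4 of 13 slow fibre genes were higher, and 11 of 16 fast fibre genes were lower and 1 higher. The mitochondrially encoded genes (median 0.41), the tricarboxylic acid cycle (0.21), endothelial markers (0.34) and red blood cell genes (0.77) were higher, with 7 of 10, 5 of 20, 4 of 18 and 3 of 6 members past the threshold adjusted over the list alone. Their camera adjusted p were 4.52e-07, 4.52e-07, 0.000119 and 0.00144, and with an estimated correlation 0.251, 0.3, 0.203 and 0.295. Glycolysis (-0.19) and immediate early genes (-0.35) were lower, with adjusted p = 9.52e-05 and 0.0287, and 0.315 and 0.467 with an estimated correlation. With library sizes from the spike-ins, the median of all genes moved by 0.21, that of glycolysis became 0.02, and 430 genes were called, 419 higher and 11 lower. The count of 95 became 17 without FLExDUX4 control 1 and 286 without FLExDUX4 running 4. It became 23 without WT running 4, 22 without WT control 1, 32 without FLExDUX4 running 2, 40 without FLExDUX4 running 1, 41 without WT control 3, 42 without FLExDUX4 control 3, 45 without WT control 2, 55 without FLExDUX4 running 3, 56 without WT running 1 and 239 without WT running 3.

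Genotype with running was read from FLExDUX4 runners against WT runners. Fatty acid oxidation, respiratory chain, heat shock and endothelial genes sat lower in FLExDUX4 runners as lists and tendon markers higher, with no gene called. The 26 fatty acid genes had a median of -0.29 and the 77 respiratory chain genes of -0.12 (camera adjusted p = 1.02e-06 and 5.82e-05; adjusted p = 0.922 and 0.966 with an estimated correlation). Heat shock genes had a median of -0.22, endothelial markers of -0.25 and tendon markers of 0.53 (camera adjusted p = 0.000182, 0.00352 and 0.00257; adjusted p = 0.687, 0.687 and 0.922 with an estimated correlation). In each of these 5 lists 0 members passed adjusted over the list alone. Which lists were called changed without single mice: in place of 1 higher and 4 lower, 3 were called higher and 2 lower without FLExDUX4 running 4 (3 of the 5 shared), and 3 higher and 3 lower without WT running 4 (4 shared). None of the 5 reversed without a single mouse. Myh2 averaged 921 CPM ± 612 (n = 4) in FLExDUX4 runners and 1119 ± 953 (n = 4) in WT runners, and Myh4 21401 ± 7066 and 19850 ± 7114, neither called (adjusted p = 0.999 for each).

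edgeR called 0 genes, with 350 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The smallest p, all uncalled, were those of Timp4 (-1.39 ± 0.30, adjusted p = 0.57), Commd2 (0.95 ± 0.22), Mcf2l (-1.80 ± 0.44), Tnfaip2 (-0.70 ± 0.17) and 9430073C21Rik (4.13 ± 1.11), with adjusted p of 0.727 for the middle 3 and 0.999 for the last. 9430073C21Rik averaged 0.102 CPM ± 0.203 in WT runners and overlaps the Myh2 locus. Commd2 (ENSMUSG00000036513, chromosome 3, 57644349 to 57651715) was also the 1 gene called in the authors' table, and averaged 23.9 CPM ± 4.01 against 12.4 ± 2.65. Col1a1 differed by 0.43 ± 0.19 and Myh7 by 0.59 ± 1.17, uncalled.

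The interaction asked whether running changed the muscle differently in the 2 genotypes. As lists, the running effect on fatty acid oxidation, respiratory chain, slow fibre and endothelial genes was smaller in FLExDUX4 than in WT, and no gene was called. The mitochondrially encoded genes did not share this, with a median difference of 0.04 and 6 of 10 above 0 (camera adjusted p = 0.977). The 26 fatty acid genes all had a lower running effect in FLExDUX4, with a median difference of -0.65 and 2 past the threshold adjusted over the list alone, Hadhb (-0.997 ± 0.30) and Plin5 (-2.03 ± 0.65) (camera adjusted p = 6.92e-13; adjusted p = 0.654 with an estimated correlation). The slow fibre genes had a median of -2.12 and the respiratory chain of -0.23 (camera adjusted p = 0.000258 and 2.89e-06, and 0.654 and 0.792 with an estimated correlation). For the slow fibre genes, the genotypes differed by a median of 2.22 in controls and 0.32 in runners, so this contrast lay mostly in the controls. Of 100 regroupings of the mice, the real one included, 39 gave at least 9 called lists. The regroupings mixed mice across genotype and running and can follow the running effect, so this share does not measure chance alone. Chance was not excluded for the lists. Glycolysis had a median of 0.29 (camera adjusted p = 0.00325; adjusted p = 0.654 with an estimated correlation), which became -0.01 with library sizes from the spike-ins, where the median of all genes moved by -0.32. Gapdh was the 1 glycolytic gene past the threshold adjusted over the list alone, at 0.77 ± 0.23 (adjusted p = 0.954 over all genes).

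In this contrast endothelial markers had a median of -0.61, tendon markers of -1.06, heat shock genes of -0.30, the tricarboxylic acid cycle of -0.22 and red blood cell genes of -0.63. Their camera adjusted p were 0.000152, 0.026, 0.0268, 0.0308 and 0.0497, and with an estimated correlation 0.462, 0.654, 0.654, 0.798 and 0.654. edgeR called 0 genes, with 537 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The smallest p, all uncalled, were those of Pim3 (-1.75 ± 0.35, adjusted p = 0.199), Timp4 (-2.004 ± 0.45), AC153524.3 (-4.27 ± 1.01), Hmgb1-ps8 (1.38 ± 0.35) and the glycosylation enzyme gene Pmm2 (-2.26 ± 0.58). Pim3 averaged 19.5 CPM ± 4.63 in WT controls, 40.3 ± 11.4 in WT runners, 48.1 ± 20.5 in FLExDUX4 controls and 29.4 ± 4.11 in FLExDUX4 runners, and was called without WT running 1 (-1.89, adjusted p = 0.0254) or without FLExDUX4 control 3 (-1.96, adjusted p = 0.0162). Without WT running 3, Myom3 was called instead (-4.35, adjusted p = 0.0284), which was named after its value was seen. Lists called fell from 9 to 5 without FLExDUX4 running 4 and likewise without FLExDUX4 control 2. Myh2 differed by -3.27 ± 1.19 and Ppargc1a by -0.57 ± 0.26, uncalled.

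Averaged over running, tendon and slow fibre genes were higher in FLExDUX4 mice as lists, the slow fibre genes mainly through the controls, with no gene called. Of 7 tendon markers, all had a fold change above 0 and 5 were higher adjusted over the list alone (median 0.82, camera adjusted p = 3.19e-12; adjusted p = 0.11 with an estimated correlation). Chad differed by 1.56 ± 0.34, Thbs4 by 0.70 ± 0.18, Cilp2 by 1.30 ± 0.45 and Kera, a matrix proteoglycan, by 0.82 ± 0.30. The mean log2 level of the 7 was 0.89 higher (exact permutation p = 0.0171, adjusted p = 0.154 over 54 tests). Whether the dissected pieces held unequal shares of tendon was not tested, and the labels do not describe the pieces. Slow fibre genes had a median of 1.47 (camera adjusted p = 7.18e-07, and 0.998 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Their median was 2.22 between controls but 0.32 between runners, where the list was not called (camera adjusted p = 0.73). The mean log2 slow fibre level was 1.10 higher over both (exact permutation p = 0.141, adjusted p = 0.309 over 54 tests). edgeR called 0 genes, with 418 at an unadjusted p under 0.05, limma-voom 0, and DESeq2 1, Chad. Besides Chad and Thbs4, the smallest p, all uncalled, were those of Pdlim1 (0.94 ± 0.24), the kinase gene Nuak1 (0.67 ± 0.17) and Gm43793 (-3.47 ± 0.89), each with an adjusted p of 0.837. Without WT running 1, Chad (1.79, adjusted p = 0.0125) and Myom3 (2.03, adjusted p = 0.0229) were called. Lists called rose from 2 to 8 without FLExDUX4 running 4, 6 without FLExDUX4 control 3, 5 without FLExDUX4 control 1 or WT control 2, and 4 without WT running 1 or FLExDUX4 control 2.

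Whether the genotype effect persisted with running, and whether running opposed it, was read across genes, which are not independent replicates. Since 0 genes were called between the control groups, none could be followed into the runners. Of the 98 genes with an unadjusted p under 0.01 between controls, 43 (43.9%) had the same sign between runners, with r = -0.02 across them, and 0 were under 0.01 in both. For genes chosen in the same way, the simulations of unchanged groups described next gave 50.4% (SD 3.30, lowest 44.9%). All simulations here draw each gene independently, so their spread is likely too narrow for genes that move together. They therefore do not place 43.9% below chance. Between the genotype effects in controls and in runners, r across all 11088 genes was -0.019. Of 100 regroupings of mice within running, the real one included, 65 gave an r as high (lowest other -0.107, highest other 0.093). Across all 11088 genes, the genotype effect in controls and the running effect in FLExDUX4 had r = -0.449. They share the FLExDUX4 controls, and 20 simulations of unchanged groups gave a mean r of -0.531 (SD 0.0142), so the negative value was no stronger than the shared group alone gives. The covariance across all genes was -0.143, against -0.139 (SD 0.00502) in the simulations, so by this measure it was not weaker either. Without single mice, the r across all genes ran from -0.625 to -0.364. In simulations with the same mouse left out, chosen after these values were seen, the mean r ran from -0.664 to -0.455, and in none of the 10 cases was the real r below the simulated values. In most cases it lay above all of them. Among 6355 genes above a mean log2 CPM of 3, r was -0.250 against -0.535 in simulations, and the covariance -0.0277 against -0.0494. The genotype effect in controls and the running effect in WT share the WT controls and had r = 0.603 against 0.553 (SD 0.0108) in simulations, and 0.686 against 0.542 (SD 0.0140) among the 6355 genes. Of the 98 genes, 17 (17.3%) had the same sign in FLExDUX4 running and 95 (96.9%) in WT running. Since the genes were chosen with the shared controls, unchanged groups gave 5.80% (SD 2.03) and 94.8% (SD 2.28). These simulations of chosen genes were added after the values were seen.

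The running effects of the 2 genotypes share no library and had r = 0.152, and 0.313 against -0.005 in simulations among the 6355 genes. Of 100 regroupings, the real one included, 2 gave an r across all genes as high, the highest other being 0.196.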

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

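The split counts and the tests of list by genotype and running were planned before the data were examined, and no test in this part was chosen after its result was seen.

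In 9 of 158 groups of 4 mice, 1 mouse stood apart from the other 3 by Dixon's test at the 95% level; chance gives about 1 in 20 groups, or 7.9. WT running 3 had 86.3 CPM of Tigar and 0.406 CPM of 9430073C21Rik, where the other 3 WT runners had 0. FLExDUX4 running 4 had a mean log2 level of 5.45 for red blood cell genes, the lowest of its group. FLExDUX4 running 2 had a mean log2 level of 7.04 for cytosolic ribosomal proteins, against 7.06 in the other 3, and 18.6 CPM of Iqsec2. FLExDUX4 running 1 had 68.6 CPM of Tnfaip2, 4.08 of 9430073C21Rik and 2.72 of AC153524.3. FLExDUX4 running 3 had 10.2 CPM of Ift20.

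The running effect differed between the genotypes for 9 lists by camera at the preset correlation. The adjusted p were 6.92e-13 for fatty acid uptake and oxidation, 2.89e-06 for the respiratory chain, 0.000152 for endothelial markers, 0.000258 for slow fibre genes, 0.00325 for glycolysis and glycogen, 0.026 for tendon markers, 0.0268 for heat shock proteins, 0.0308 for the tricarboxylic acid cycle and 0.0497 for red blood cell genes. None of these held with an estimated correlation, where the smallest adjusted p of any list was 0.462. Chance was not excluded for the lists: 39 of 100 regroupings of the 14 mice, the real one included, gave at least 9 lists, the highest other 16. Such regroupings can also follow the running effect, so this share does not measure chance alone. For single genes the regroupings test nothing, since all 100 necessarily reach the 0 calls of the real grouping; the highest other gave 103. That many calls point to a structure of the samples, which was not separated from the labelled running effect that such a regrouping can follow.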

How the results depend on the processing

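The alternatives without mitochondrial genes and Gm42418, with spike-in library sizes, without FLExDUX4 control 1 and WT running 2, and with the slow fibre level as a covariate were chosen after the data were seen. No paired analysis was possible because the labels give no link between the mice of different groups.

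With RLE or upper quartile factors and with the filter of 1 CPM, every count of called genes stayed within 1.5 times its value, and 0 stayed 0. For running in WT (55 genes), no filter gave 217, a threshold of 0.10 gave 149, DESeq2 196 (143 higher, 53 lower), limma-voom 23, 1 surrogate variable 4, spike-in library sizes 604 and the slow fibre covariate 2. Leaving out single mice gave 0 to 197. For running averaged over genotype (95 genes), no filter gave 291, a threshold of 0.10 gave 236, DESeq2 273, 1 surrogate variable 2, spike-in library sizes 430, the 2 libraries left out 24 and the slow fibre covariate 10, and leaving out single mice 17 to 286. The comparisons with 0 calls gained some. Genotype in controls had 12 with no filter, 2 without the robust estimate (Myom3 and Lmod2), 3 with DESeq2, 3 with a surrogate variable (Mb, Myoz2 and Myom3), 23 with only the 2 groups in the fit, 2 with spike-in library sizes (Pim3 and Pdlim1) and 0 to 1 without single mice. Running in FLExDUX4 had 24 with no filter, 1 with a surrogate variable (Egln3) and 6 with only the 2 groups. Genotype in runners had 2 with no filter (Timp4 and Tnfaip2). The interaction had 11 with no filter, 2 with a surrogate variable (Mb and Myom3), 1 with spike-in library sizes (Pim3) and 0 to 1 without single mice. Genotype averaged over running had 8 with no filter, 1 with DESeq2, 4 with a surrogate variable (Chad, Erdr1, Myoz2 and Myom3), 1 with the slow fibre covariate (Erdr1) and 0 to 2 without single mice. Genes in brackets were named after their values were seen. Except for the looser threshold of 0.10, the cause was not tested.

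Of the lists, 0 were called with an estimated correlation in each of the 7 comparisons, and fry called 3 for running in WT, 5 for running averaged over genotype and 0 in the others. With the slow fibre covariate, list calls were 3 for genotype in controls, 3 for the interaction and 8 for genotype averaged over running. The last had 4 without mitochondrial genes and Gm42418 and 4 without the 2 libraries. Without single mice, list calls were 7 to 9 for genotype in controls, 5 to 12 for running in FLExDUX4, 13 to 18 for running in WT, 5 to 7 for genotype in runners, 5 to 11 for the interaction, 2 to 8 for genotype averaged over running and 13 to 18 for running averaged over genotype. The respiratory chain list reversed in 1 case, genotype in controls with the slow fibre covariate, where its direction was lower (adjusted p = 0.0121); the cause was not tested. Genes with an unadjusted p under 0.01 in place of called ones gave 43 with the same sign between runners where 0 could be followed, and genes above a mean log2 CPM of 3 gave an r of -0.250 in place of -0.449. Without single mice, the r across all genes was -0.625 to -0.364. Over single named genes that were called, 781 of 1201 values under alternatives chosen before the data were examined and 132 of 232 under added ones kept the call, and 0 reversed.

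Of the 7 DUX4-responsive genes, 5 had too few counts to test, and whether depth limited them was not tested.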

Other observations

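The tests of fibre content, of mitochondrial counts, of the clock phase and of the slow fibre level were chosen after the results they concern were seen, and the split counts were planned.

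Muscle pathology lists gave no camera call between FLExDUX4 and WT controls. The adjusted p were 0.844 for 23 macrophage and monocyte markers, 0.984 for 25 genes of extracellular matrix and fibrosis, 0.683 for 16 fibro-adipogenic progenitor and fibroblast markers, 0.892 for 14 genes of regeneration and embryonic myosins, 0.923 for the neuromuscular junction and denervation, and 0.0553 for atrophy, ubiquitin ligases and autophagy. Over the 7 comparisons, 15 of 33 lists were never called by camera, among them p53 targets, cell cycle, the unfolded protein response, proteasome, adipocyte, lipogenesis and basement membrane genes. Lymphocyte and keratinocyte markers had too few counts for a list test.

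Further lists were called for running averaged over genotype, none with an estimated correlation. They were heat shock proteins (median log2 change 0.07, camera adjusted p = 0.00184), regulators of mitochondrial biogenesis and endurance (0.20, 0.0208), smooth muscle and pericyte markers (0.22, 0.0327), interferon response and antigen presentation (0.26, 0.0447) and Schwann cell and nerve markers (0.43, 0.0447). With an estimated correlation their adjusted p were 0.299, 0.315, 0.282, 0.353 and 0.299. Members past the threshold adjusted over the list alone included Hspb1 (0.42 ± 0.12), the interferon-induced Rtp4 (1.93 ± 0.52) and Mbp (1.08 ± 0.29).

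The runners of each genotype differed among themselves in myosin composition. Myh2 made up 10.8% of the 4 adult myosin transcripts in WT running 1 and 8.06% in WT running 4 against 2.03% and 0.610% in WT running 2 and 3. It made up 9.94% and 4.47% in FLExDUX4 running 2 and 1 against 2.54% and 0.663% in 3 and 4. A split of the 8 runners that put WT running 1 and 4 with FLExDUX4 running 1 and 2 gave 87 called genes, where the real split by genotype gave 0. In WT mice, the split that put WT running 3 with the 3 controls gave 135 calls, more than the real 55. The split of the runners points to a structure of the samples other than genotype, and the split of the WT mice differs from the real one in the place of 1 mouse. Distances run are not in the labels.

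For running averaged over genotype, the shares fell under the planned limit of 0.05. Of 100 regroupings within genotype, 2 gave at least 95 genes (highest other 207) and 4 at least 16 lists (highest other 17). These shares include the real grouping and were not adjusted over the comparisons, so they count against chance without excluding it. Chance was also not excluded for running in WT, where 2 of 35 splits gave at least 55 genes (highest other 135) and 7 of 35 at least 14 lists (highest other 17). Nor was it excluded for the lists of running in FLExDUX4, where 22 of 35 splits gave at least 7 (highest other 13), of genotype in runners, where 27 of 35 gave at least 5 (highest other 21), or of genotype averaged over running, where 94 of 100 gave at least 2 (highest other 15). For the genes of these 3 comparisons the splits test nothing, since a real count of 0 is necessarily reached by all 35, 35 and 100 (highest others 1, 87 and 2). For genotype in controls the 10 splits are too few for a share under 0.05: the real split gave 0 genes (reached by all 10, highest other 2) and 8 lists (1 of 10, highest other 7).

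The 55 genes called in WT runners may reflect running, the slow fibre content of the piece taken, or a few abundant transcripts. Without mitochondrial genes and Gm42418, 54 of the 55 were still called, so the calls did not rest on the counts of those rows. Other abundant transcripts, such as Myh4, were left in, so abundant counts in general were not tested. With the slow fibre level of each mouse as a covariate, 74.3% of the median fold was left (0.89 to 0.66, standard error 0.21 to 0.20) and all 55 kept their direction, but 2 stayed called, as the median fold shrank and its standard error hardly changed. In the FLExDUX4 mice, which share no library with this comparison, the mean signed level of the same genes was 0.35 higher in runners (1-sided exact permutation p = 0.0857), and 49 of 55 had the same sign. Running and fibre content therefore cannot be told apart for these genes.

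The clock genes may reflect a different time of day at collection, another shift of clock phase, or running itself. Genes of opposite phase moved apart: Arntl, Clock, Npas2, Cry1 and Nfil3 averaged 0.60 higher on the log2 scale in runners, and Per, Dbp, Tef, Hlf, Nr1d, Ciart, Usp2 and Bhlhe41 genes averaged -1.12 relative to controls (difference of the sets 1.72, exact permutation p = 0.00327, adjusted p = 0.154 over 54 tests). That is consistent with a phase shift. Runners of each genotype moved the same way, by at least 1.601, so that running and an unequal collection time cannot be told apart without the collection times, which are not in the labels.

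The higher slow fibre genes in FLExDUX4 than in WT controls may reflect genotype or an unequal share of slow fibres in the piece dissected. The mean log2 level differed by 1.97 without overlap, with a range of 0.290 among WT controls and 1.49 among FLExDUX4 controls. In the runners, the level differed by 0.22 between genotypes (exact permutation p = 0.886), which neither excludes nor shows a genotype effect with 4 mice each. Genotype and dissection cannot be told apart here, since the labels do not describe the pieces taken and the range among FLExDUX4 controls was neither as large as the difference nor small beside it.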
